A study of Homo sapiens with 6 samples.

How the data were processed

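RNA levels were measured on 6 one-colour oligonucleotide arrays, 1 per condition, in primary human keratinocytes that had been isolated from skin. Per the labels' protocols, cells on 3 dishes per condition received retroviruses or mock transductions 12 h apart, total RNA was extracted 48 h after the last transduction, and biotinylated cRNA was prepared from 6 ug of it. The labels do not say whether the dishes were pooled, and 1 array per condition was used here. The deposited values are signal intensities, 1 per probe set, made with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into a single linear signal and scales each array to a common target. Its version, its target and any filter are not given in the sources used here.

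Each array was rescaled to a common mean after trimming 2% of the probe sets at each end. The deposited arrays already had nearly equal trimmed means of about 500 units (500.1 to 500.2), so this step changed little. Signals below the 40th percentile of all values (64.8) were then set to that floor, because dim MAS5 signals carry mostly background, and log2 was taken. A difference was computed only where at least 1 of the arrays compared lay above the floor. Where 1 side lay at the floor, the fold is a lower bound and is written "at least". A gene was called detected at or above the 60th percentile (233.6). Of the 100 results named for the largest differences, 85 had a dimmer signal under this level, 21 of them at the floor, so the size of those folds depends on the floor. Where a detected probe set of a gene named with a fold lay more than 1 log2 closer to 0 than the one used, the text gives the other values.

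The table held 22272 probe sets. Through the platform annotation, 19065 of them had 1 gene symbol, 1043 had several and 2164 had none (56 of them array controls), and only the first kind was used for genes. For 19053 the Entrez identifier was found in a RefSeq table of the GRCh38.p14 assembly, which changed 0 symbols. That table was used for names and chromosomes only. Of several probe sets of a gene, the brightest by mean log2 signal was taken, which left 11939 genes. Of these, 3005 lay at the floor on all 6 arrays and had no differences. Genes on the Y chromosome and an X-linked gene were left out for privacy. All columns of values were mapped to a sample.

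With 1 array per condition no test between a pair of conditions exists, and none was run. Genes at least 2-fold apart were counted as a description. For each of 30 gene lists, the median log2 difference of the measured members was set against 10000 random lists of the same size, drawn from genes matched on mean signal in 20 bins. A list median below the 2.5 or above the 97.5 percentile of these is called outside the random range, which describes these arrays and carries no p-value. The mean signal used for matching was taken over all arrays. Where a list is bright on other arrays, its matched genes can be brighter than its members in the pair compared. Lists with fewer than 5 measured members got no percentile. The lists cover early differentiation, the cornified envelope, basal cells and their adhesion, the activated keratinocyte of wounds, cell junctions, AP-1 subunits, AP-1 targets, ERK feedback genes, EGF receptor ligands, cytokines, invasion proteases, mesenchymal genes, hypoxia and angiogenesis, S phase, G2 and mitosis, p53 and senescence, apoptosis, interferon-stimulated genes, the unfolded protein response, heat shock, oxidative and metal stress, sterol synthesis, JNK and p38 regulators, TGF-beta and BMP signalling, ribosomal proteins, markers of fibroblasts, melanocytes, endothelial and immune cells, and the expressed target genes.

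The groups, lists, thresholds, other settings to be tried and the rule for named genes were fixed before the data were examined. By that rule the text names, for the 5 main comparisons, the 10 genes with the largest difference in each direction whose brighter array was detected and whose detected probe sets all moved the same way. It also names up to 3 of the highest and lowest detected members of each list, the target genes, the 10 genes with the smallest adjusted p per effect of the model below, and the 5 largest departures from additivity in each direction. Any other gene named was chosen after its values were seen, and the text says so.

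The only test used all 6 arrays. A linear model with additive effects of MKK7, Ras and DNc-Jun on log2 signal was fitted with limma (lmFit and eBayes), which left 2 residual degrees of freedom per gene and a prior worth 2.602. Adjusted p-values follow Benjamini and Hochberg over 8934 genes, with 0.05 as the threshold, and were also adjusted over each list alone. The residual of this model contains any interaction between the vectors, and its p-values measure the spread between these 6 arrays. For the same vector in 2 settings, correlations were computed across genes from 4 arrays with no array in both differences. Genes are not independent replicates, so these correlations carry no p-value. The departure from additivity was the log2 signal of MKK7+Ras minus MKK7 minus Ras plus LacZ.

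The procedures were tested on simulated data. For MKK7 against LacZ (8164 genes), noise was drawn independently for each gene with an SD of 0.367 log2, taken from the spread of the observed differences. Then 3 of 100 unchanged lists of 20 genes fell outside the random range and all 100 lists shifted by 0.5 log2 lay above it. In the same simulation 62 unchanged genes were at least 2-fold apart. Such noise includes any effect of MKK7, and it does not vary with signal or run together between genes of a list, as real values may. For the Ras effect of the additive model (8934 genes), 98 of 100 genes changed by 3 log2, 39 of 50 changed by 2 and 2 of 50 changed by 1 were recovered, and 16 of 155 calls were false.

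The number of arrays limits the precision. The pooled SD between probe sets of a gene, for log2 differences between 2 arrays, ran from 0.325 to 0.438 over the 8 comparisons, and the SD over 18 spike-in probe sets from 0.129 to 0.204. The mean over the spike-in probe sets shifted by up to 0.526 log2 (MKK7+Ras against Ras), for which no correction was made. These measure probe behaviour and hybridisation, not differences between cultures. Other settings tried were quantile normalization, values as deposited, floors at the 20th and 60th percentiles, the median of a gene's probe sets, lists without probe sets whose names end in _x_at or _s_at, the model without dim genes and the model without each array in turn. Counts without dim genes, counts that avoid the LacZ array, families of genes by name, probe sets of genes named from the model and a common ratio applied to the Ras difference of 26 lists were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, plots matplotlib 3.10.9, and the model R 4.3.3 with limma 3.58.1.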

Results

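RNA levels were measured in primary human keratinocytes, the main cell type of the epidermis, that had been isolated from skin and transduced with retroviruses. The 6 conditions were LacZ, a bacterial enzyme that served as the control, a constitutively active MKK7, a kinase that switches on JNK, the V12 form of the oncogene Ras, a dominant negative form of the AP-1 subunit c-Jun (DNc-Jun), MKK7 with Ras, and all 3 vectors together. The stated purpose of the series was to learn which genes respond to Ras and MKK7. Each condition had 1 array, so no difference between a pair of conditions has a replicate check. The vectors were given 12 h apart, with mock transductions filling the places of missing vectors. In MKK7+Ras the Ras vector therefore came 12 h later than in Ras alone, and DNc-Jun came last in the condition with all 3 vectors.

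The arrays had similar depth. Median signals ran from 117.6 to 140.8 units (MKK7+Ras and DNc-Jun), and 5481 to 5897 genes were detected per array. The 3'/5' signal ratio of the ACTB control, a measure of RNA integrity, was between 1.02 and 1.23, and that of GAPDH between 0.780 and 0.949. The LacZ array differed at the bright end. Its highest signal was 25579 against 14697 to 19069 on the other arrays, and the brightest 1% of its probe sets took 21.8% of the summed signal against 15.4% to 18.6%.

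The expressed genes were examined first. HRAS, the Ras gene represented by a named probe set, had a signal of 14698 on the Ras array, 14542 with MKK7+Ras and 14396 with all 3 vectors, against 1883 with LacZ, 1875 with MKK7 and 1499 with DNc-Jun. The Ras signal was thus 7.80-fold above LacZ and was the brightest on its array. JUN, which encodes c-Jun, behaved differently by probe set. The probe set 201465_s_at was 163-fold higher with DNc-Jun than with LacZ and 141-fold higher with all 3 vectors, but 3.21-fold higher with Ras and 1.56-fold higher with MKK7, all over an undetected LacZ signal of 89.6. The probe set 201464_x_at was 5.28-fold higher with Ras, 1.94-fold with MKK7 and 1.40-fold with DNc-Jun, and 201466_s_at was 8.90-fold, 2.52-fold and 2.37-fold higher. The probe set 213281_at was higher with MKK7 (4.71-fold) than with Ras (2.93-fold) or DNc-Jun (2.61-fold), over an undetected LacZ signal of 77.7. Whether a probe set read the vector, the cell's own gene or both was not measured. The level of the MKK7 gene itself is not analysed here.

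**Figure D1:**
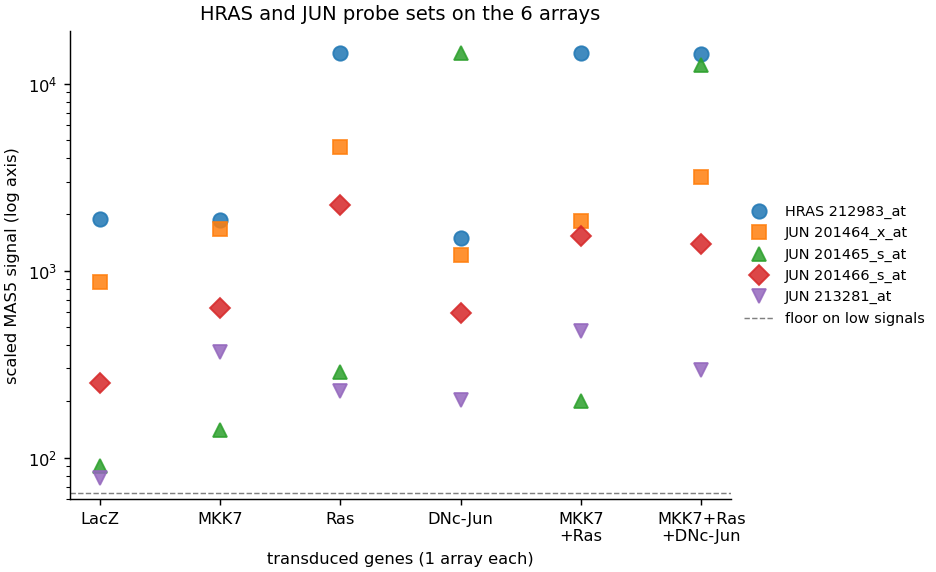
Signal (log axis, arbitrary units) of the HRAS probe set and of 4 JUN probe sets on the 6 arrays, 1 point per array, with the floor of 64.8 as a dashed line. HRAS lies between 14396 and 14698 on the 3 arrays with Ras and between 1499 and 1883 on the others, and 201465_s_at of JUN is at 14613 and 12614 on the 2 arrays with DNc-Jun and at 287 or less on the others.

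MKK7 alone was compared with LacZ to find genes that respond to this kinase. Cytokine genes were higher as a group: 5 of 16 measured members were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 difference of 0.89 at percentile 100 of the random lists. A member at the floor with LacZ was measured only if MKK7 lay above the floor, so it could only be higher. Random lists were matched on mean signal over all arrays, and CXCL8 and IL1R2 were at 284 and 460 with MKK7 but 3742 and 3259 with Ras. The matched genes can thus be brighter than these members with LacZ and MKK7, so percentile 100 may overstate how far the list stands apart. IL24, a cytokine of the interleukin-10 family, was 4.60-fold higher. CXCL8, which attracts neutrophils, was at least 4.38-fold higher, and IL1R2, a decoy receptor for interleukin-1, was 3.62-fold higher. The secreted proteases ADAMTS1 and MMP10 were 3.58-fold and 2.90-fold higher. ATF3, a stress-induced relative of the AP-1 proteins, was 3.11-fold higher, and DUSP1 and DUSP10, phosphatases that inactivate JNK and p38, were 2.65-fold and 2.26-fold higher. IL24, CXCL8, IL1R2 and ATF3 were undetected with LacZ, and their signals with MKK7 were only 1.38, 1.21, 1.97 and 1.345 times the detection level.

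Other genes with large differences after MKK7 were MAP1B, a microtubule-binding protein (3.87-fold higher), KYNU, an enzyme of tryptophan breakdown (3.36-fold, with its probe sets between 0.53 and 1.75 log2), RFC5, a subunit of the clamp loader of DNA replication (3.35-fold, with the other probe sets of the gene as low as 0.14 log2), RPAIN (3.92-fold) and CLDN4, a tight junction protein (3.06-fold). In the other direction MYL12A, a myosin light chain, was 2.84-fold lower, TFAP4 2.78-fold, GIT1 2.70-fold, NRGN 2.64-fold, RRP9 2.62-fold, PPP2R1A, the scaffold subunit of a major phosphatase, 2.60-fold, WNT6 2.55-fold, and MYO9B (with its probe sets between -1.29 and -0.24 log2) and BCAM 2.45-fold. RARA, a retinoic acid receptor, was 2.88-fold lower by its brightest probe set, and 0.26 log2 higher when its probe sets were summarised by their median.

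The proliferation lists differed little after MKK7. No member of the list for G2 and mitosis (30 measured) or S phase (27) was 2-fold apart, with medians of -0.07 and 0.04. The medians for early differentiation (0.26), the cornified envelope (-0.07), basal cells (-0.21), the activated keratinocyte (-0.07), junctions (0.07), AP-1 targets (0.03), EGF receptor ligands (-0.01), proteases (0.12), mesenchymal genes (0.14), hypoxia (0.04), apoptosis (-0.01), the unfolded protein response (-0.14), heat shock (0.03), oxidative and metal stress (-0.06), sterol synthesis (-0.13) and TGF-beta signalling (0.04) lay inside the random range. Medians for AP-1 subunits (0.41), p53 and senescence (0.21), ERK feedback (-0.19), interferon-stimulated genes (-0.08), JNK and p38 regulators (-0.26) and ribosomal proteins (-0.41) lay outside it, each losing that place under at least 1 alternative. The sign turned for AP-1 subunits without probe sets ending in _x_at or _s_at (-0.16), for JNK and p38 regulators with the floor at the 20th percentile (0.12) and for ribosomal proteins under quantile normalization (0.04).

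In all, 124 genes were at least 2-fold higher and 74 lower after MKK7 among 8164 measured. The simulation of this comparison gave 62 such genes. Its noise was sized from these same differences and was alike for every gene, so 62 is not a measure of array noise. The counts were 404 and 705 with the floor at the 20th percentile and 37 and 22 with the floor at the 60th. Without the LacZ array, MKK7+Ras against Ras gave 128 higher and 272 lower genes. That pair also has Ras on both arrays and 12 h less of it in MKK7+Ras, so its counts are not those of MKK7 alone.

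Ras alone was compared with LacZ to find genes that respond to the oncogene. Every measured gene of G2 and mitosis was at least 2-fold lower with Ras (30 of 30, median log2 difference -3.48), as were 23 of 27 genes of S phase (median -2.05), both at percentile 0 of the random lists. CDC20, an activator of the anaphase-promoting complex, was 23.1-fold lower, the spindle proteins DLGAP5 and HMMR 20.9-fold and 19.0-fold, CEP55, needed for abscission, 18.1-fold, and BIRC5, of the chromosomal passenger complex, at least 18.3-fold (with its probe sets between -4.19 and -2.86 log2). CCNB1 and CDK1, which together drive entry into mitosis, were 16.5-fold and 16.1-fold lower. TYMS and RRM2, which make DNA precursors, were 19.0-fold and 14.5-fold lower, TOP2A, which untangles DNA, 15.3-fold (-2.80 log2 by its other detected probe set) and CDC6, a licensing factor of replication origins, 11.2-fold.

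Genes of inflammation, of the differentiated epidermis and of cell junctions were higher. Of 19 measured cytokine genes, 14 were at least 2-fold higher and 0 lower (median 2.55, percentile 100). CXCL8 was at least 57.7-fold (3.61 log2 by its other detected probe set), IL1R2 25.6-fold and CXCL2, another chemokine for neutrophils, 17.9-fold higher. Of 15 cornified envelope genes 8 were at least 2-fold higher (median 1.24, percentile 100), led by CRCT1 (34.2-fold), the desquamation protease KLK7 (18.1-fold) and the lipoxygenase ALOXE3 (4.21-fold). Among early differentiation genes 4 of 9 were at least 2-fold higher (median 0.84), with ZNF750 and PRDM1, transcription factors of epidermal differentiation, at least 6.24-fold and 3.65-fold higher and involucrin (IVL) 2.46-fold higher. CLDN4, CLDN1 and CLDN7 were 22.4-fold, at least 7.82-fold and 6.79-fold higher in the junction list (7 of 20 higher, median 0.46).

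Signalling genes differed in both directions with Ras. AP-1 subunits were higher as a list (7 of 11, median 1.35), led by ATF3 (29.0-fold), MAFF (5.58-fold) and JUN (5.28-fold), although FOSL1 was at -0.25 log2. The list lay inside the random range without probe sets ending in _x_at or _s_at. AP-1 targets had a median of 0.83 (12 of 24 higher and 1 lower), with MMP10 5.74-fold and the wound keratin KRT16 5.55-fold higher and DNMT1 2.46-fold lower. DUSP1 and DUSP10 were 16.9-fold and 11.4-fold higher. In the ERK feedback list (median 0.45, 4 of 22 higher and 2 lower) EGR3 was at least 10.6-fold, SPRY2 6.06-fold and EGR1 3.56-fold higher, whereas ETV4, MYC and DUSP6 were at -1.36, -1.27 and -0.76 log2. Genes of p53 and senescence had a median of 0.60: GADD45B was 9.35-fold and the cell cycle inhibitors CDKN1C and CDKN1A 2.98-fold and 2.43-fold higher, and CDKN2A, another inhibitor, was 2.67-fold lower. The protease list had a median of 0.33 (9 of 22 higher), with ADAMTS1 5.64-fold and MMP9 4.91-fold higher. Activated keratinocyte genes had a median of 0.64 (4 of 9 higher), led by SLPI, an inhibitor of proteases, at 7.45-fold. The last pair lay inside the random range with the floor at the 60th and at the 20th percentile, respectively.

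Among the largest single differences after Ras were also IGFBP3, a carrier of insulin-like growth factors (at least 50.5-fold higher, and 4.0 log2 by its other detected probe set), FA2H, a fatty acid hydroxylase of barrier lipids (at least 19.4-fold), and NDRG4 (17.7-fold). Interferon-stimulated genes had a median of -0.36 (7 of 26 lower and 4 higher), with the antiviral OAS2, OAS3 and TRIM22 3.64-fold, 2.80-fold and 2.41-fold lower and RSAD2 at least 4.78-fold higher. The list of the unfolded protein response lay inside the random range with a median of 0.20, and 6 of 19 members were at least 2-fold higher and 5 lower. CHAC1, PPP1R15A and DDIT3 were 8.84-fold, 5.87-fold and 3.86-fold higher, and PDIA4 and HSP90B1, chaperones of the endoplasmic reticulum, were 4.8-fold and 4.56-fold lower (HSP90B1 by -1.15 log2 in its other detected probe set). In the TGF-beta list (median 0.05) BAMBI and BMP2 were 6.82-fold and 4.02-fold higher and the activin antagonist FST 12.6-fold lower. Mesenchymal genes (median 0.07) held ITGA5 at 2.72-fold higher and LOXL2, a collagen crosslinker, at 4.64-fold lower. DST, a hemidesmosome linker, was 4.71-fold (with its probe sets between -2.40 and 0.87 log2) and the basal keratin KRT5 2.21-fold lower in the basal list (median -0.30), whereas the integrin ITGA2 was 2.27-fold higher.

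The remaining lists after Ras had medians of 0.26 (EGF receptor ligands), -0.39 (hypoxia), 0.07 (apoptosis), -0.29 (oxidative and metal stress), 0.14 (sterol synthesis) and 0.12 (JNK and p38 regulators), inside the random range. Heat shock genes (-0.61) and ribosomal proteins (-0.69) lay below it, but inside it under quantile normalization. Markers of other cell types differed little: fibroblast markers had a median of 0.03 (8 measured), melanocyte markers 0.26 (6), immune markers -0.08 (5) and endothelial markers 0.40 (3), with 0 members 2-fold apart. Altogether 904 genes were at least 2-fold higher and 658 lower with Ras among 8454 measured. Without the LacZ array, MKK7+Ras against MKK7 gave 303 higher and 458 lower genes, with MKK7 on both arrays and Ras given 12 h later than in Ras alone.

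**Figure D2:**
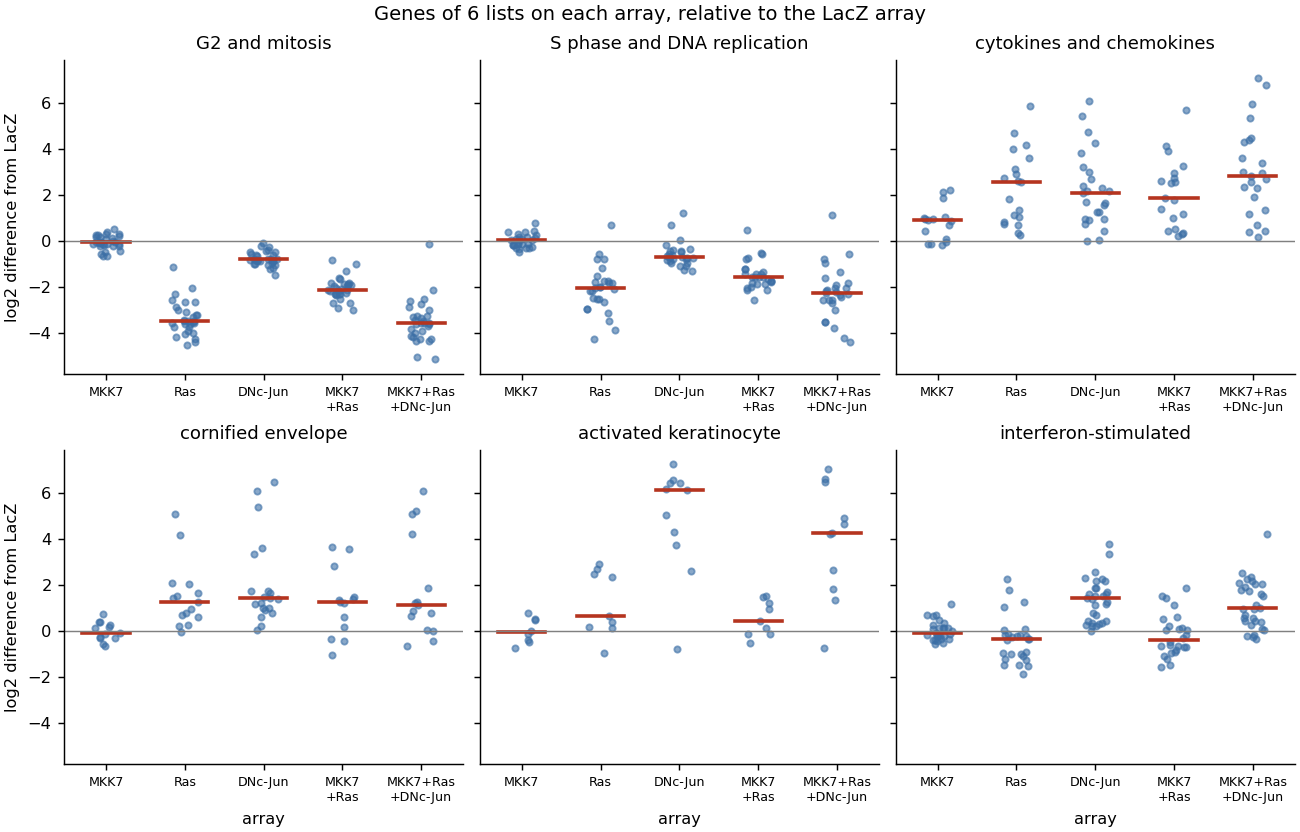
Difference from LacZ (log2) of each measured gene of 6 lists on the other 5 arrays, 1 point per gene, with the list median as a red bar. Genes of G2 and mitosis have a median of -3.48 with Ras and -3.58 with all 3 vectors but -0.07 with MKK7, and activated keratinocyte genes have a median of 6.10 with DNc-Jun.

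MKK7 and Ras together were compared with LacZ. Proliferation genes were again lower, with 28 of 30 genes of G2 and mitosis (median -2.11) and 22 of 27 of S phase (median -1.58) at least 2-fold lower. FOXM1, a transcription factor of the mitotic program, was 8.69-fold lower, the spindle motor KIFC1 at least 8.35-fold, the nuclear lamin LMNB1 at least 8.34-fold, CDC20 7.95-fold, the motor KIF20A 7.48-fold, TACC3 7.23-fold, PKMYT1, a kinase that restrains CDK1, 6.72-fold, UBE2C 6.42-fold, PTPRO 6.42-fold and the cyclin CCNB2 6.39-fold. Cytokine genes were higher (13 of 19, median 1.88), with CXCL8 at least 51.2-fold (4.60 log2 by its other detected probe set), CXCL2 14.8-fold and IL1R2 17.2-fold higher, and IL1RL1, the receptor of interleukin-33, was 19.1-fold above an undetected LacZ signal of 66.8. Other large differences were IGFBP3 (at least 30.3-fold, and 3.57 log2 by its other detected probe set), ATF3 (28.8-fold), CALB1, a calcium-binding protein (21.2-fold), CLDN4 (18.7-fold), DUSP1 (14.5-fold) and KLK7 (12.3-fold).

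Cornified envelope genes were higher in MKK7+Ras (8 of 13 higher and 1 lower, median 1.26), as were junction genes (7 of 20 higher, 1 lower, median 0.44), AP-1 subunits (4 of 10, median 0.74) and AP-1 targets (8 of 24 higher, 2 lower, median 0.38). CRCT1 and SPRR2B were 11.7-fold and 7.07-fold higher, CLDN1 at least 10.4-fold, the desmosomal DSC2 5.81-fold, MAFF 4.87-fold, MMP10 8.17-fold and PLAUR, the urokinase receptor, 3.40-fold, whereas TGFB1 was 3.17-fold lower. Proteases (0.38, with ADAMTS1 7.64-fold higher), p53 and senescence (0.36, with GADD45B 7.03-fold higher), basal genes (-0.40, with COL7A1 2.51-fold lower and ITGA2 3.69-fold higher) and interferon-stimulated genes (-0.41, with OAS3 2.93-fold lower) also lay outside the random range, each losing that place under 2 or more alternatives. Early differentiation (0.47), the activated keratinocyte (0.43), ERK feedback (0.14), EGF receptor ligands (-0.40), mesenchymal genes (0.22), hypoxia (-0.29), apoptosis (0.15), the unfolded protein response (0.25), heat shock (-0.23), oxidative and metal stress (-0.18), sterol synthesis (0.19), JNK and p38 regulators (-0.04), TGF-beta signalling (-0.17), ribosomal proteins (-0.35) and fibroblast markers (0.18) lay inside it. In this comparison 560 genes were at least 2-fold higher and 644 lower among 8233.

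DNc-Jun was compared with LacZ, which asks what differs when c-Jun function is blocked without an added oncogene. Genes of the activated keratinocyte had the largest list median of all comparisons: 10 of 11 were at least 2-fold higher, with a median of 6.10. S100A7 and S100A9, antimicrobial calcium-binding proteins, were at least 150-fold and 94.1-fold higher, the serpins SERPINB4 and SERPINB3 at least 86.2-fold and 71.0-fold, LCN2, which binds bacterial siderophores, 86.1-fold and the elastase inhibitor PI3 68.8-fold. Cytokine genes were higher (18 of 25, median 2.08), with CCL20, which attracts dendritic cells, at least 67.8-fold, CXCL8 at least 42.3-fold (3.63 log2 by its other detected probe set) and the adhesion molecule ICAM1 26.6-fold higher (with its probe sets between 2.59 and 4.91 log2). Differentiation genes were higher too, with 14 of 20 cornified envelope genes (median 1.42) and 8 of 11 early genes (median 1.79) at least 2-fold higher, among them SPRR2B (88.9-fold), CDSN, of corneodesmosomes (at least 66.8-fold), KLK7 (41.3-fold), ZNF750 (at least 16.0-fold), the crosslinking enzyme TGM1 (at least 14.4-fold) and CALML5 (at least 8.13-fold).

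Interferon-stimulated genes were also higher with DNc-Jun, 19 of 30 by at least 2-fold and 0 lower (median 1.41, percentile 100). RSAD2 was at least 13.6-fold, the chemokine CXCL10 at least 10.1-fold and OASL 5.94-fold higher. Further large differences were CST6, an inhibitor of cysteine proteases (91.6-fold over an undetected LacZ signal of 70.6), GDF15, a stress-induced member of the TGF-beta family (at least 73.9-fold), and HMOX1, which degrades haem (36.2-fold). AP-1 targets had a median of 0.71 (12 of 25 higher, 1 lower) and AP-1 subunits 0.70 (3 of 10 higher, 1 lower), with ATF3 31.7-fold, MAFF 5.64-fold and FOS 4.81-fold higher and FOSL1 2.52-fold lower. In the protease list (median 0.47, 9 of 22 higher, 2 lower) the inhibitors TIMP3 and TIMP2 were 8.90-fold and at least 8.15-fold higher and MMP14 was 2.37-fold lower. The median was 0.63 for p53 and senescence (7 of 16 higher), with GADD45B 10.1-fold and CDKN1C 4.61-fold higher.

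Basal, mesenchymal and proliferation genes were lower with DNc-Jun. Basal genes had a median of -0.81 (3 of 13 lower by at least 2-fold), with DST 2.52-fold (with its probe sets between -1.49 and 0.29 log2), ITGA2 2.04-fold and CD151 2.01-fold lower. Mesenchymal genes had a median of -0.98 (5 of 13 lower), with the matrix protein TNC 4.26-fold, LOXL2 2.95-fold and vimentin (VIM) 2.42-fold lower and CCN2, a matricellular growth factor, 7.14-fold higher, and this list lay inside the random range without probe sets ending in _x_at or _s_at. Medians were -0.80 for G2 and mitosis (6 of 30 lower) and -0.69 for S phase (4 of 27 lower, and CCNE1 2.33-fold higher). Single genes with the lowest values were PLEC, a linker of keratin filaments (5.69-fold lower, with its probe sets between -2.51 and -0.13 log2), the WNT antagonist DKK1 (5.52-fold), the adenosine receptor ADORA2B (5.28-fold), ANXA6 (5.10-fold), VEGFB (5.06-fold), DCBLD2 (4.11-fold), MBP (4.04-fold), HP1BP3 (at least 4.03-fold) and CAPN15 (4.03-fold).

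The other lists were closer to 0 with DNc-Jun. Junction genes had a median of 0.19 (5 of 20 higher, CLDN4 7.61-fold) and apoptosis genes 0.37 (1 of 16 higher), both inside the random range under at least 1 alternative, as were ribosomal proteins at -0.51, or -0.02 under quantile normalization. Medians inside the range were 0.08 for ERK feedback (EGR3 at least 26.6-fold and LIF at least 19.1-fold higher, DUSP4 3.04-fold lower), 0.07 for EGF receptor ligands, -0.07 for hypoxia (ADM 7.93-fold and ANGPTL4 at least 8.46-fold higher), 0.16 for the unfolded protein response (DDIT3 5.11-fold higher, PDIA4 2.67-fold lower), -0.10 for heat shock (HSPA4L 4.54-fold higher), -0.22 for oxidative and metal stress, -0.34 for sterol synthesis, 0.25 for JNK and p38 regulators, -0.27 for TGF-beta signalling, 0.17 for fibroblast, 0.20 for melanocyte and 0.12 for immune markers. Of the immune markers CD14 was at least 7.25-fold and CD52 at least 4.12-fold higher, and both endothelial markers measured (median -0.54) were less than 2-fold apart. With DNc-Jun, 772 genes were at least 2-fold higher and 336 lower among 8572, so that 69.7% of these genes were higher. Under quantile normalization the counts were 646 and 470, or 57.9% higher, and read without the LacZ array, as all 3 vectors against MKK7+Ras, 337 and 173. That pair carries MKK7 and Ras on both arrays, and DNc-Jun came last there, so its exposure may differ from that of DNc-Jun alone.

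All 3 vectors were compared with MKK7+Ras, which asks what DNc-Jun alters in cells that carry both signals. Activated keratinocyte genes (9 of 11 at least 2-fold higher, median 4.35) and interferon-stimulated genes (18 of 30, median 1.20) were higher, and genes of G2 and mitosis (22 of 30 lower, median -1.66) and S phase (9 of 25 lower, median -0.81) were lower. S100A7 and S100A9 were 95.9-fold and 95.3-fold above undetected signals of 87.3 and 123.7, LCN2 33.8-fold, GDF15 at least 104-fold, CDSN at least 68.1-fold, ICAM1 49.4-fold (with its probe sets between 3.37 and 6.25 log2), the protease KLK6 43.1-fold, the cytokine LIF at least 40.3-fold, HMOX1 33.0-fold and CCL20 19.2-fold. The transcription factor EGR4 (at least 74.1-fold, and 4.68 log2 by its other detected probe set), the dehydrogenase DHRS2 (53.8-fold) and the phosphatase DUSP2 (at least 38.6-fold) were also among the 10 highest. IRF1, RSAD2 and CXCL10 were 5.62-fold, 5.05-fold and at least 5.63-fold higher. CEP55 was 7.78-fold lower, CDK1 7.42-fold (with its probe sets between -2.89 and -1.73 log2), SHCBP1 5.76-fold, the mitotic kinase PBK at least 4.84-fold, the kinetochore motor CENPE 4.82-fold, RRM2 4.71-fold, HJURP and BUB1B 4.52-fold, CDC20 at least 4.46-fold and the cyclin CCNA2 4.18-fold.

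Smaller list medians in this comparison were 0.79 for AP-1 subunits (FOS 3.19-fold and JUNB 3.11-fold higher), 0.46 for the cornified envelope (SPRR2B 4.81-fold higher), 0.41 for cytokines (10 of 23 higher), 0.27 for the unfolded protein response (DDIT3 3.76-fold higher) and 0.21 for heat shock. Medians outside the random range that returned inside it under 1 or more alternatives were 0.54 for early differentiation, 0.29 for JNK and p38 regulators, 0.26 for p53 and senescence, 0.22 for apoptosis, 0.11 for AP-1 targets (TIMP1 5.80-fold, IL6 3.68-fold and MMP9 3.05-fold higher), -0.25 for mesenchymal genes (AXL 2.57-fold lower) and -0.25 for sterol synthesis. Basal genes (-0.21), junctions (-0.07), ERK feedback (0.11), EGF receptor ligands (0.13), proteases (0.07), hypoxia (-0.09), oxidative and metal stress (-0.10), TGF-beta signalling (0.09), ribosomal proteins (-0.15), immune markers (0.59, CD52 at least 4.69-fold higher) and fibroblast markers (-0.02) lay inside it. The counts were 337 higher and 173 lower among 8162 genes.

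**Figure D3:**
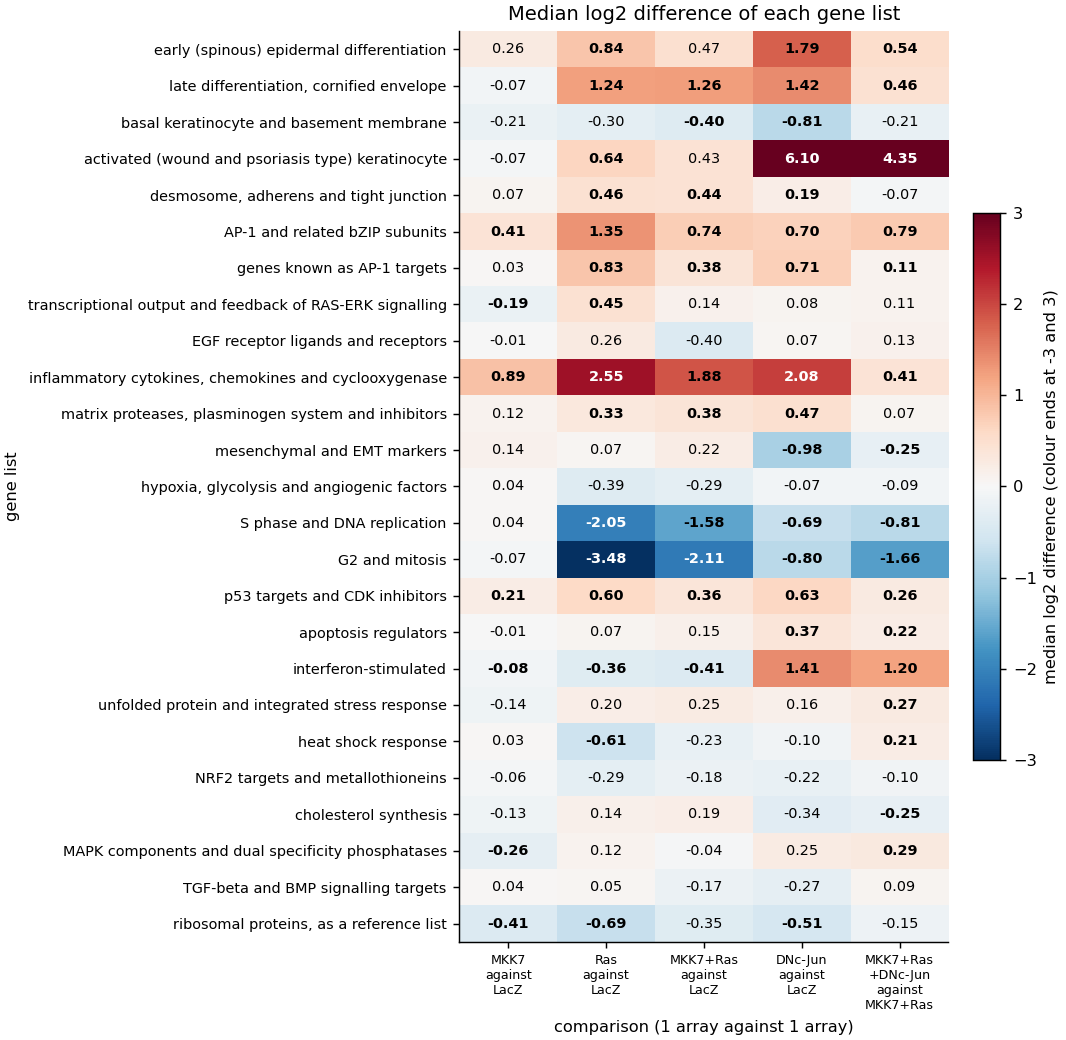
Median log2 difference of 25 gene lists (vertical) in the 5 main comparisons (horizontal), with the colour scale ending at -3 and 3 and values outside the random range in bold. The proliferation medians run from -3.48 with Ras to -0.07 with MKK7 for G2 and mitosis, and the interferon-stimulated list is at 1.41 and 1.20 in the 2 comparisons that add DNc-Jun and between -0.41 and -0.08 in the others.

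Adding MKK7 to Ras was read as MKK7+Ras against Ras, with 12 h less of Ras in the former. Genes of G2 and mitosis were higher beside MKK7 (21 of 30 at least 2-fold, median 1.31), as were those of S phase (7 of 26, median 0.58), while AP-1 subunits (-0.56), AP-1 targets (-0.41), the cornified envelope (-0.41) and the activated keratinocyte (-0.50) were lower. Mesenchymal (0.30), interferon-stimulated (0.21) and ribosomal genes (0.35) lay above the random range and the unfolded protein response (-0.14) below it, each returning inside it under 1 or more alternatives. There were 128 higher and 272 lower genes among 8227. The mean of the spike-in probe sets was 0.526 log2 higher in MKK7+Ras than in Ras, and no correction was made for it. Adding Ras to MKK7 gave 303 higher and 458 lower genes among 7995, with medians of -2.07 for G2 and mitosis, -1.52 for S phase, 1.46 for cytokines, 1.02 for the cornified envelope, 0.41 for junctions and 0.54 for the unfolded protein response. All 3 vectors against LacZ gave 889 higher and 815 lower genes among 8422, with medians of -3.58 for G2 and mitosis, -2.24 for S phase, 4.23 for the activated keratinocyte, 2.82 for cytokines, 1.14 for the cornified envelope, 1.01 for early differentiation (inside the random range without probe sets ending in _x_at or _s_at) and for p53 and senescence, 0.98 for interferon-stimulated genes, 0.96 for proteases and 0.71 for the unfolded protein response.

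The same vector was then read in 2 settings that share no array. For Ras, the differences without and with MKK7 had a Pearson correlation of 0.759 and a Spearman correlation of 0.657 across 7850 genes, and 244 genes were at least 2-fold higher in both, against 34.4 for independent lists, and 321 lower in both, against 38.0. For DNc-Jun, without and with MKK7+Ras, the correlations were 0.627 and 0.467 across 7963 genes, with 235 genes higher in both (31.6 for independent lists) and 44 lower in both (6.94). For MKK7, without and with Ras, they were 0.144 and 0.117 across 7792 genes, with 10 higher in both (2.0) and 11 lower in both (2.24). Another 5 genes were at least 2-fold higher with MKK7 without Ras and lower with it, and 0 the other way. Of the genes higher without Ras 48.4% were above 0 with it, and of those lower without Ras 85.3% were below 0. MKK7+Ras without and with DNc-Jun had 0.579 and 0.505 across 7894 genes, with 108 higher in both (11) and 223 lower in both (31.2). With the floor at the 20th percentile the Ras correlation was 0.578 and that of MKK7+Ras 0.395.

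**Figure D4:**
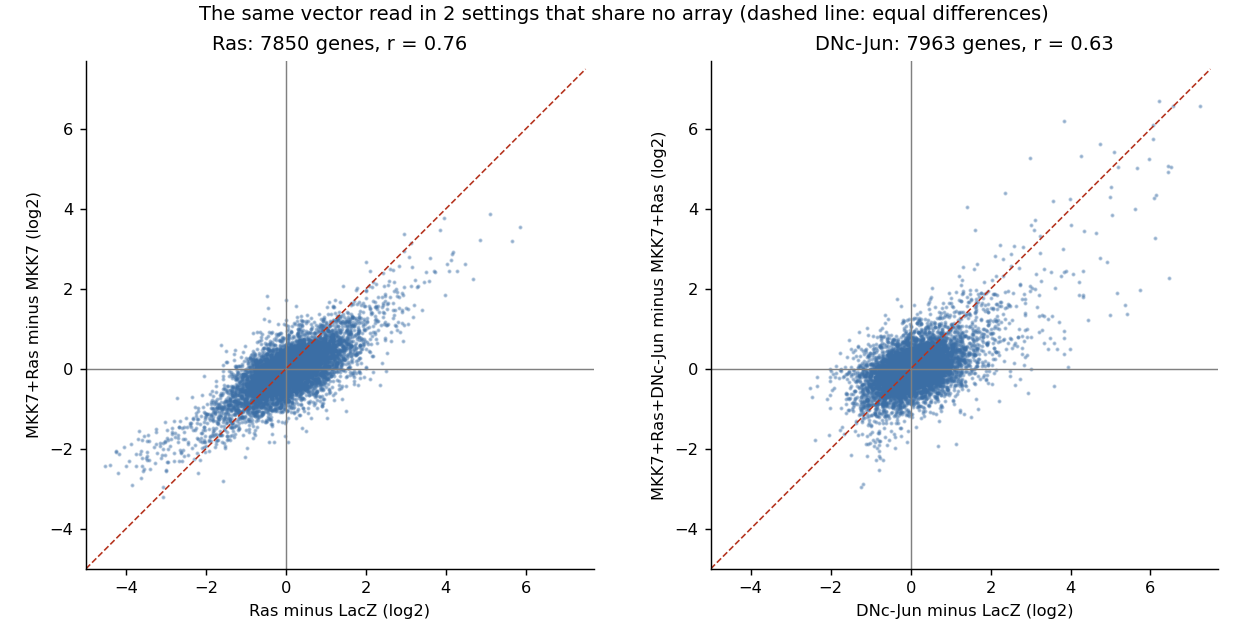
Log2 difference made by Ras without MKK7 (horizontal) against with MKK7 (vertical), and by DNc-Jun without against with MKK7+Ras, 1 point per gene, with the dashed line at equal values; differences with 1 side at the floor are bounds. Pearson correlations across genes are 0.759 for Ras (7850 genes) and 0.627 for DNc-Jun (7963 genes). Ras came 12 h later beside MKK7, and DNc-Jun came last beside MKK7+Ras.

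To ask whether DNc-Jun turns back the genes that differ with Ras, those genes were read in the comparison of all 3 vectors with MKK7+Ras. Of 900 genes at least 2-fold higher with Ras, 100 (11.1%) were at least 2-fold higher again when DNc-Jun was added and 12 (1.33%) lower, against 4.13% and 2.12% of all genes, and their median of 0.13 lay at percentile 100. Of 633 genes lower with Ras, 84 (13.3%) were lower again and 13 higher, with a median of -0.31 at percentile 0.

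Departure from additivity, the part of MKK7+Ras not given by the sum of the single differences, was at least 1 log2 in size for 755 of 8599 genes, 214 above the sum and 541 below it. Genes of G2 and mitosis lay above the sum (median 1.35), as did S phase (0.55), ribosomal proteins (0.71, but -0.06 and inside the random range under quantile normalization) and interferon-stimulated genes (0.23). The activated keratinocyte (-0.91), cytokines (-0.86), AP-1 subunits (-0.77), the cornified envelope (-0.43), AP-1 targets (-0.32) and proteases (-0.19) lay below. MYL12A (2.30), HMMR (2.20), TYMS (2.16), the water channel AQP3 (2.13) and CDC20 (2.10) were highest. GOLGA8N (-2.74) and GOLGA8A (-2.56), near-identical copies whose probes cannot be relied on to separate them, AFAP1 (-2.55), IGFBP3 (-2.45) and IL1R2 (-2.43) were lowest. The value rests on all 4 arrays including LacZ, and the AFAP1 and IGFBP3 values depend on the floor. It holds the error of each of these arrays, and no count expected from noise was made. The 755 genes are therefore not a count of interactions. Ras also came 12 h later in MKK7+Ras than in Ras alone, so a departure does not separate an interaction from the time of exposure. The count was 1975 with the floor at the 20th percentile and 361 with the floor at the 60th.

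The additive model fitted to all 6 arrays gave 463 genes for Ras, of which 128 rose and 335 fell, at a smallest limma adjusted p of 0.0282. Genes of G2 and mitosis fell in 28 of 30 cases (29 adjusted over the list alone) and genes of S phase in 22 of 27 (25 adjusted over the list alone). CDKN3 fell by 2.80 log2 (SE 0.163), TACC3 by 2.69 (SE 0.171), the kinetochore protein ZWINT by 2.63 (SE 0.176), OIP5 by 2.56 (SE 0.161) and the mitotic motor KIF18A by 2.04 (SE 0.133). GEM, a small GTPase, rose by 3.18 (SE 0.136), HRAS by 3.04 (SE 0.146), IL13RA2, a decoy receptor for interleukin-13, by 2.81 (SE 0.179), LCP1, an actin bundler, by 2.27 (SE 0.152) and BMP2 by 1.98 (SE 0.132). All 10 had a limma adjusted p of 0.0282, and for each the 3 arrays with Ras lay on the same side of the 3 without. Over all 8934 genes, 26.0% were separated in this way, where a random order of 6 arrays without ties would give 10%. Ties at the floor and the other vectors alter that share, so 10% is only a rough reference.

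In the other lists the members past the limma threshold for Ras were few, and they are named here after their values were seen. Of the cytokines only CXCL2 rose among 25 (12 adjusted over the list alone). Of 25 AP-1 targets HBEGF, MMP1 and PLAUR rose and DNMT1 fell (8 and 1 adjusted over the list alone). In the ERK feedback list DUSP5 and EGR1 rose among 22 (9 rose and 2 fell adjusted over the list alone). In the unfolded protein response DDIT3, CHAC1 and PPP1R15A rose and HSP90B1 and SDF2L1 fell among 19 (9 and 4 adjusted over the list alone). Both detected probe sets of HSP90B1 were lower on average on the arrays with Ras than on those without (by 2.15 and 1.025 log2). In the single pair of MKK7+Ras and LacZ, however, 1 of them was 1.81 log2 higher with MKK7+Ras. In the TGF-beta list ID2, BMP2 and INHBA rose and TGFBI, ID1 and FST fell among 16 (4 and 4 adjusted over the list alone). CDKN1A and GADD45A rose by 1.14 and 0.84 log2, and CRCT1 and ALOXE3 by 3.81 and 1.60. With the floor at the 20th percentile 0 genes passed for Ras, against 2369 at an unadjusted p under 0.05 in the main setting, and with any single array left out 0 passed.

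For DNc-Jun 119 genes passed, 112 that rose and 7 that fell. GDF15 rose by 6.46 log2 (SE 0.165, limma adjusted p 0.00359), S100A7 by 6.86 (SE 0.190, adjusted p 0.00359), CDSN by 5.90 (SE 0.193, adjusted p 0.00504) and S100A9 by 6.32 (SE 0.240, adjusted p 0.00504). TNFAIP2, a target of TNF signalling, rose by 5.61 and DHRS2 by 5.72, both at 0.00504, the small heat shock protein HSPB8 by 3.28 and the anti-inflammatory cytokine IL37 by 3.81, both at 0.00543, ICAM1 by 5.11 at 0.00720 and the protease inhibitor SERPINA3 by 3.88 at 0.00866. In each of these the 2 arrays with DNc-Jun lay above the 4 without. Over all genes the 2 sets of arrays did not overlap for 18.4%, where a random order of 6 arrays without ties would give 13.3%, again only a rough reference. Several of the genes named above lay at the floor on up to 4 arrays, so the fitted size, its SE and the adjusted p depend on the floor. GDF15, HSPB8, IL37 and SERPINA3 were at the floor on all 4 arrays without DNc-Jun, which leaves no spread between those arrays.

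Interferon-stimulated genes rose with DNc-Jun in 12 of 30 cases (28 adjusted over the list alone), among them ISG15 (1.82 log2), IFIT2 (2.29 log2) and the transcription factors IRF1 and IRF7 (2.04 and 1.25 log2). Of 11 activated keratinocyte genes 6 rose (9 adjusted over the list alone), S100A7, S100A8, S100A9, SERPINB3, SERPINB4 and LCN2. Of the cytokines 7 of 25 rose (9 adjusted over the list alone), IL36G, IL6, CCL5, CCL20, TNF, ICAM1 and LIF. In the lists of early differentiation and the cornified envelope 1 gene each rose, OVOL1, below the detection level on all arrays, and CDSN (4 each adjusted over the list alone). HMOX1 rose by 4.83 log2 and VEGFC, a growth factor of lymphatic vessels, fell by 1.47. The count was 42 with the floor at the 20th percentile and 0 to 8 with an array left out, 8 of them without MKK7+Ras.

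For MKK7, 0 genes passed in limma, with 583 at an unadjusted p under 0.05 and a smallest adjusted p of 0.737, held by PRB1 (-0.96 log2), SUGCT (1.36), SHB (-0.97), CA5BP1 (-1.04), NXPE3 (0.94), GPNMB (0.86), AP4S1 (0.88), ZBTB22 (-0.91), CCDC9 (-0.87) and TUBA1A (0.97). The 3 arrays with MKK7 and the 3 without overlapped for SUGCT, GPNMB, AP4S1 and ZBTB22. Over all 8934 genes they did not overlap for 5.75%, where a random order of 6 arrays without ties would give 10%. Ties at the floor lower that share and the other vectors can alter it, so MKK7 is not shown to lie below chance.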

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

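The bootstrap tests of the Ras ratio were chosen only after the results were seen, and the test of ribosomal genes and the splits of the arrays were planned. The MKK7 difference had opposite signs without and with Ras for 3 lists whose medians lay outside the random range both times. AP-1 subunits had a median log2 difference of 0.41 for MKK7 against LacZ and -0.56 for MKK7+Ras against Ras, interferon-stimulated genes -0.084 and 0.207, and ribosomal protein genes -0.41 and 0.35. The contrast did not hold under every alternative: without Ras the AP-1 median was -0.16 without probe sets ending in _x_at or _s_at, the ribosomal median was 0.0365 under quantile normalization, and the interferon median lay inside the random range under 4 of 5 alternatives, as did the ribosomal median with Ras. Each value rests on 1 pair of arrays, and the difference between the settings was not tested. MKK7+Ras also had 12 h less of Ras than Ras alone, so the values with Ras are not those of MKK7 alone. For these lists Ras against LacZ had medians of 1.35, -0.36 and -0.69, so a weaker response to Ras would give the same signs.

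Ribosomal protein genes were lower than with LacZ on all 5 other arrays, and the median lay under the 2.5 percentile on 3 of them. If the bright end of the LacZ array were scaled differently from its other probe sets, these abundant transcripts would lose their place once the arrays have equal distributions. Under quantile normalization 0 of the 5 arrays stayed under the 2.5 percentile, with percentiles of 71.4 for MKK7, 25 for Ras, 55.3 for DNc-Jun, 25.6 for MKK7+Ras and 12.7 for all 3 vectors. Quantile normalization would also even out a real fall shared by abundant transcripts, so this result cannot tell such a fall from scaling. Signal-dependent scaling of the LacZ array stays a candidate explanation for this list, and no biological explanation was tested.

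In the 6 lists with a Ras median of at least 1 log2 in size over genes measured both times, the Ras median was smaller beside MKK7, whereas some small medians were larger there, with 0.20 and 0.54 for the unfolded protein response (0.438 and 0.491 under quantile normalization), 0.07 and 0.32 for mesenchymal genes (0.05 and 0.15) and 0.14 and 0.24 for sterol synthesis (0.13 and 0.24). A shorter or weaker exposure to Ras, which came 12 h later in that condition, could shrink all of them alike, and then the ratio of list medians with and without MKK7 would be the same for each of them. The ratios were 0.593 for G2 and mitosis (bootstrap interval 0.539 to 0.638), 0.744 for S phase (0.599 to 0.882), 0.603 for cytokines (0.400 to 0.907), 0.723 for the cornified envelope (0.498 to 1.13), 0.195 for early differentiation (-0.054 to 0.647) and 0.145 for AP-1 subunits (-0.001 to 0.971). The 6 lists were picked by the size of the Ras difference without MKK7, so part of the shrinkage can come from that choice. The bootstrap drew genes of a list on the same arrays, so its intervals hold no error between arrays or cultures. In 0 pairs of these 6 lists did the wide intervals fail to overlap, and when 0.593, taken without its error, was applied to 26 lists the interval of the remainder excluded 0 for 3, and of these only for the cornified envelope (0.212) also under quantile normalization, while the unfolded protein response left 0.14 (-0.045 to 0.313), or 0.02 under quantile normalization. A common shrinkage therefore stays open, as does an effect of MKK7 itself on the response to Ras, which was not separated from the timing, and HRAS signals, near the top of the array range, were about equal.

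Probe sets that have no gene name in the annotation used here, array controls left aside, were not part of any comparison. Of these, 15 were at least 2-fold higher with MKK7 than with LacZ, 61 with Ras, 50 with MKK7+Ras and 63 with DNc-Jun, and 21 with all 3 vectors than with MKK7+Ras, and 12, 62, 53, 46 and 22 were lower in the same order. The largest difference was 6.75 log2 with MKK7 and 6.57 with MKK7+Ras. Between 847 and 908 of the 2108 were measured in a comparison.

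The additive model was refitted with the arrays divided in other ways. For Ras the real division gave 463 genes and the highest of the others 0, so that 1 of 9 splits that could be fitted reached that count. For MKK7 the real division gave 0 genes and the highest other 0, so that all 9 of 9 did, but a count of 0 is reached by any split, and this test says nothing about MKK7. With so few splits a share under 0.05 cannot be reached. For Ras, the other splits left the Ras term out of the model, so the Ras differences fell largely into the residual. Their counts of 0 were therefore likely whatever the noise, and add no support to the 463 genes.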

How the results depend on the processing

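Counts without dim genes and counts that avoid the LacZ array were chosen only after the results were seen; the other alternatives were planned. Counts, higher then lower, moved with the floor and when the same vector was read in another pair of arrays without LacZ. At the 20th percentile they were 404 and 705 for MKK7, 1425 and 1114 for Ras, 894 and 1264 for MKK7+Ras, 1298 and 784 for DNc-Jun, 808 and 439 for all 3 vectors against MKK7+Ras, 356 and 836 for MKK7+Ras against Ras, 635 and 749 for MKK7+Ras against MKK7, and 1325 lower for all 3 vectors against LacZ. At the 60th they were 37 and 22, 588 higher for Ras, 344 and 389, 408 and 219, 177 and 71, 44 and 142, 180 and 267, and 558 and 519 for all 3 vectors against LacZ. Without dim genes MKK7 had 69 and 41, and MKK7+Ras against Ras 85 higher. In the pairs without the LacZ array MKK7 had 272 lower, Ras 303 higher and DNc-Jun 337 and 173. These pairs also carry other vectors on both arrays, and those for MKK7 and Ras have 12 h less of Ras in MKK7+Ras. In the pair for DNc-Jun this vector came last on the array with all 3, so its exposure may differ from that of DNc-Jun alone. The move can therefore not be assigned to the LacZ array. In the additive model Ras had 0 genes at the 20th percentile floor, 929 without dim genes and 0 to 0 with an array left out; DNc-Jun had 42, 79 at the 60th, 281 without dim genes and 0 to 8. A left-out array leaves 1 residual degree of freedom less, and a lone array is then taken to vary like the others. Departures from additivity numbered 1975 and 361 at the 2 floors. Correlations at the 20th percentile floor were 0.578 for Ras, 0.496 for DNc-Jun and 0.395 for MKK7+Ras, at the 60th 0.783 for Ras, 0.0981 for MKK7 and 0.636 for MKK7+Ras, and 0.776 for Ras under quantile normalization.

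The sign reversed for AP-1 subunits with MKK7 (-0.16) and AP-1 targets with all 3 vectors against MKK7+Ras (-0.0002) without probe sets ending in _x_at or _s_at, for JNK and p38 regulators with MKK7 at the 20th percentile floor (0.12), for ribosomal proteins with MKK7 under quantile normalization (0.0365), and for RARA with MKK7 by the median of probe sets (0.26). The cause was not tested. Of 98 list medians outside the random range over the 8 comparisons, 85 stayed outside at the 20th percentile floor, 84 at the 60th, 82 with the median of probe sets, 85 under quantile normalization and 74 without probe sets ending in _x_at or _s_at. Of 100 gene results, 11, 78, 25 and 0 moved under the first 4 of these. Values as deposited left the counts of 2-fold genes as they were. No paired analysis was possible because each condition had 1 array.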

Other observations

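The gene families and single genes below, and the tests of the interferon-stimulated list, were chosen only after the results were seen. The measured clustered histone genes were higher as a group wherever Ras or DNc-Jun was present, while S phase genes were lower there. Many other members of the family lay at the floor on every array and had no differences. Which histone transcripts the probe sets read was not measured. The medians therefore do not show that bulk histone output rose while S phase genes fell. With Ras 9 of 14 measured members were at least 2-fold above LacZ (median log2 difference 1.76, or 1.72 under quantile normalization), with DNc-Jun 13 of 18 (1.73 and 1.58), with MKK7+Ras 7 of 15 (0.97 and 1.04), and with all 3 vectors against MKK7+Ras 12 of 17 (1.42 and 1.38). With MKK7 alone 0 of 11 were (0.09). The signal of H2AC6 was 111 with LacZ, 143 with MKK7, 725 with Ras, 2204 with DNc-Jun, 645 with MKK7+Ras and 3503 with all 3 vectors, and that of H2BC12 was 640, 738, 2246, 2440, 1678 and 4492 in the same order. Histone variant genes, made outside the clusters, were lower with Ras (median -1.0, 4 of 7 lower), among them H2AX (2476 with LacZ and 597 with Ras) and H2AZ2 (2214 and 960). Copies of clustered histone genes are alike in sequence, so a probe set may read several of them, and the sign was the same under quantile normalization (1.72 for Ras).

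Kallikrein-related peptidases, which release corneocytes from the skin surface, were higher with Ras (5 of 9, median 1.43) and with DNc-Jun (7 of 9, median 1.65), and KLK6 and KLK13 stood apart within them. KLK6 was at 211 with LacZ, 711 with Ras and 216 with MKK7+Ras, but at 7221 with DNc-Jun and 9300 with all 3 vectors, and KLK13 was at the floor with LacZ and at 2118 and 1060 on the DNc-Jun arrays. Transcription factors of the KLF family were higher with Ras (6 of 9, median 1.27), KLF9 from 76.4 to 477 and KLF6 from 1927 to 5669. With DNc-Jun KLF10 was at 5669 against 1409 with LacZ and KLF7 at 425 against 1114. Genes with ZNF symbols, mostly zinc finger proteins, had medians of 0.36 with Ras (28 of 176 at least 2-fold higher, 2 lower) and 0.37 with DNc-Jun (24 of 180 higher, 2 lower; 0.18 under quantile normalization). Metallothioneins, which bind zinc and copper, were lower than with LacZ, with medians of -1.05 for Ras, -0.82 for DNc-Jun, -0.73 for MKK7+Ras and -0.62 for MKK7, or -0.67, -0.50, -0.45 and -0.21 under quantile normalization. They include the brightest signals of the LacZ array, such as MT2A at 25363, and are close copies of each other. The complement gene C3 was at least 5.65 log2 higher with DNc-Jun than with LacZ and at least 5.02 higher with all 3 vectors than with MKK7+Ras, and the proton pump gene ATP12A was 5.74 log2 above an undetected LacZ signal of 69.3 with DNc-Jun. Among symbol prefixes with at least 8 measured genes, 25 of 151 families lay outside the random range with DNc-Jun, where 7.55 would by chance, and 16 of 137 with MKK7, where 6.85 would.

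Interferon-stimulated genes were higher on both arrays with DNc-Jun than on their counterparts. A larger number of retroviral vectors cannot give the list median of 1.41 for DNc-Jun against LacZ, since each of these had 1 vector. For all 3 vectors against MKK7+Ras the number also differs, and there it was not separated from DNc-Jun. MKK7+Ras, with 2 vectors, had a median of -0.41 against LacZ, but Ras alone already had -0.36. Against Ras, MKK7+Ras had 0.21, so these pairs do not settle the effect of vector number. Immune cells in the dishes were looked for by their markers. Of 13 leukocyte markers only 1, CD52, was detected and at least 2-fold higher on both arrays, while PTPRC and LYZ stayed at the floor on all 6. CD14 was at 470 with DNc-Jun and at 169.8, under the detection level, with all 3 vectors, and at the floor on the other arrays. The markers thus show no broad rise, but immune cells too few to lift them above the detection level are not excluded. The labels name no day or hybridisation batch, and with 1 array per condition no value here separates a batch from the vector. An effect of the vector itself stays open and was not tested.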
